A study of Planococcus halocryophilus and Exiguobacterium artemiae and Geobacillus stearothermophilus with 23 samples.

How the data were processed

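Small RNA was isolated from exponential and stationary cultures of 4 Bacillales species, per the labels in triplicate. Of the 24 samples planned, 1 stationary B. subtilis sample gave too little DNA, which left 23 libraries. According to the labels, a part of each culture was harvested during exponential growth and the rest grew on for 24 h, so that libraries of both phases with the same number may stem from the same culture, and replicates of a group may not be independent cultures. The p-values therefore measure only the spread between these samples. Each of the 3 MiSeq runs held the replicates of the same number of all groups, so the replicate number stands for the sequencing run. The labels also describe an rRNA depletion of part of the samples by their number in a list. If the numbering follows the order of the sample list, these are the replicates numbered 3, and depletion and run 3 cannot be told apart.

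The deposited values are counts: per the labels, the authors ligated an adapter to the RNA 3′ end, amplified for 15 to 16 PCR cycles, trimmed reads with cutadapt 1.11, and counted reads per tRNA gene and kind of 3′ end, with 1 table per library and no normalization. The mapper, its mismatch setting, the genome build and the annotation are not given in the sources used here. A further column of whole read counts, deposited by the authors under a name made of ambiguity codes (D, CD or CCV), was entered as a unit of its own kind (other). It is part of the class of other tails. In all 1762 lines of the tables the ends without added base, C, CC, CCA and other tails summed to the reads of the gene, and the repeated CCA tails and the D, CD or CCV tails together never exceeded the other tails. Incomplete ends are the sum of the first 3 of these classes, and erroneous ends are all other tails, repeats of CCA included.

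Many genes of a species carried the same values, and these were taken as the same reads listed once per gene. No sequences were used here to check this. Sums over all genes were 2.09 to 3.71 times the reads of distinct tRNAs. Genes of a species with the same values in all its libraries were merged to a distinct tRNA. This gave 38 tRNAs from 86 genes in B. subtilis, 35 from 72 in P. halocryophilus, 37 from 69 in Exiguobacterium 255-15 and 45 from 81 in G. stearothermophilus, where 3 merged sets held genes of more than 1 anticodon. Between species, reads were summed by anticodon. The merged sets Pro-TGG/CGG, Ser-TGA/CGA and Gly-TCC/CCC of G. stearothermophilus were counted under TGG, TGA and TCC, so these anticodons include the others there. Distinct tRNAs gave 91137 to 1268008 reads per library, and the exact binomial 95% interval of the complete share had a half-width of at most 0.22 percentage points. Intervals cover counting error only, since PCR copies are not independent molecules. Replicates differed by far more, with a chi-square per degree of freedom of at least 47.63 between replicates of a group. It was 47.63 to 577.26 between runs 1 and 2, and 951.99 to 14146.87 for pairs with a run 3 library.

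Shares of reads per library were compared by two-sided exact permutation tests with all arrangements enumerated: species labels within growth phase, phase labels within species, and phase labels within species for the difference of differences. The pooled test over species also exchanged phase labels within species. p-values were adjusted by Benjamini-Hochberg. End shares per tRNA (phases, each species alone) and per anticodon (species, 1 fit of all libraries with 8 group means) were compared on log2 odds with 0.5 added to both counts, for tRNAs with a mean of at least 20 reads, by limma 3.58.1. Abundances were compared with edgeR 4.0.16 (quasi-likelihood test, TMM, default expression filter) and as an alternative with DESeq2 1.42.0. Calls had an adjusted p under 0.05. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3. 7 lists of amino acids (branched-chain, aromatic, long variable arm, GUN anticodon, acidic or amide, basic, small) were tested on the same fits with fry, which asks whether a list moves in the same direction, and with camera, which compares it with the other tRNAs, at a preset correlation of 0.01 and with an estimated correlation. An initiator list was not analysed here, since the Met-CAT genes are not told apart by function, nor were lists by discriminator base, since no sequences were used here.

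The groups, comparisons, tests, lists, alternatives and the rule for naming tRNAs were chosen before the data were examined. The rule names every tRNA or anticodon past the threshold where a direction has at most 8, otherwise the 8 with the largest absolute log2 change. It adds tRNA-His, tRNA-Cys and the initiator of each species, and the 3 tRNAs of each species with the highest erroneous share among those with a mean of at least 100 reads. The alternatives were pseudocounts of 0.1 and 2, read minimums of 1 and 100, edgeR on both counts of each tRNA, other size factors, complete ends only, each tRNA weighted equally, log2 odds, ends without added base left out, the replicate number as a block, phases averaged per replicate number, each library left out in turn, and replicate 3 of every group left out. Added after seeing the data were the G. stearothermophilus libraries of run 3 left out, and fits of exponential or stationary libraries alone. The main values used all libraries, and values from fewer libraries are named as such.

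Whether replicate numbers pair the libraries was checked from the files. Deviations from the group means correlated between phases at the same replicate number by −0.464 to 0.981 for log2 reads (above 0.1 in 10 of 11 pairs) and by −0.052 to 0.874 for the log2 odds of complete ends (9 of 11). The numbers were taken as shared runs from the labels, and the block was kept as an alternative.

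The code was tested on simulated data with 20 draws per setting, an SD of 0.3 on the logit scale for end shares and a dispersion of 0.1 for abundance. These spreads were set and not estimated from the libraries, so the shares recovered are not the power of the fits reported. In the abundance fits between phases of G. stearothermophilus the standard errors of the log2 changes were 0.92 to 2.78. A log2 change of 2 in end shares was recovered for 97.5% of changed tRNAs in the phase comparison of B. subtilis, 100% in P. halocryophilus and in Exiguobacterium 255-15, and 59.4% in G. stearothermophilus, and a change of 1 for 36.9%, 46.4%, 41.4% and 0.6%. In abundance a change of 2 was recovered for 88.8%, 97.1%, 100% and 98.3%, and a change of 1 for 14.4%, 37.1%, 37.9% and 30.6%. For P. halocryophilus against B. subtilis a change of 1 was recovered for 74.2% of end shares and 76.7% of abundances, and a change of 2 for 100% of both. Unchanged tRNAs were called in at most 2.14% of cases. Noise was drawn for each tRNA and library alone, without shifts of whole libraries or runs, so this rate does not carry over to the fits reported. The exact test between species passed 0.05 in 100% of 200 draws with a shift of 4 SD and in 4.5% without a shift. The other comparisons were not simulated.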

Results

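The 3′ ends of tRNAs were sequenced in 4 species of the Bacillales, each grown at its own temperature. B. subtilis 168 was grown at 37 °C, G. stearothermophilus at 55 °C, and the cold-adapted P. halocryophilus and Exiguobacterium 255-15 at 20 °C. Exponential and stationary cultures gave 3 libraries per species and phase, apart from stationary B. subtilis with 2, so that 8 groups held 23 libraries. A mature tRNA ends in CCA, which tRNA nucleotidyltransferase adds or repairs and which aminoacylation requires. Reads of each tRNA were split into complete CCA ends, incomplete ends (the tRNA body alone, C or CC) and erroneous ends, which carried any other tail. A tRNA is named by its amino acid and anticodon, with a number where genes of the same anticodon had different counts. Libraries held 91137 to 1268008 tRNA reads, and the exact binomial 95% interval of the complete share had a half-width of at most 0.22 percentage points. Such intervals cover counting error only, since copies made by PCR were counted as reads.

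The G. stearothermophilus libraries of sequencing run 3, which holds the replicates numbered 3, stood apart from the others. In them 26 (stationary) and 24 (exponential) of the 45 distinct tRNAs had fewer than 20 reads, against 0 in the other 21 libraries. Met-CAT-3 made up 47.9% of the stationary and 43.9% of the exponential library of run 3, against 6.80% ± 0.32 and 8.42% ± 1.55 in runs 1 and 2 (SD, n = 2 each). Ends without any added base made up 13.7% of the exponential library of run 3. The other species also differed between run 3 and runs 1 and 2. Their chi-square per degree of freedom was 951.99 to 14146.87 for pairs with run 3, against 48.14 to 577.26 between runs 1 and 2. In run 3, His-GTG took 35.4% of the exponential B. subtilis reads, 15.2% of the exponential P. halocryophilus reads and 16.0% of the exponential Exiguobacterium 255-15 reads. Values of G. stearothermophilus over all 6 libraries include the 2 libraries of run 3.

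**Figure D1:**
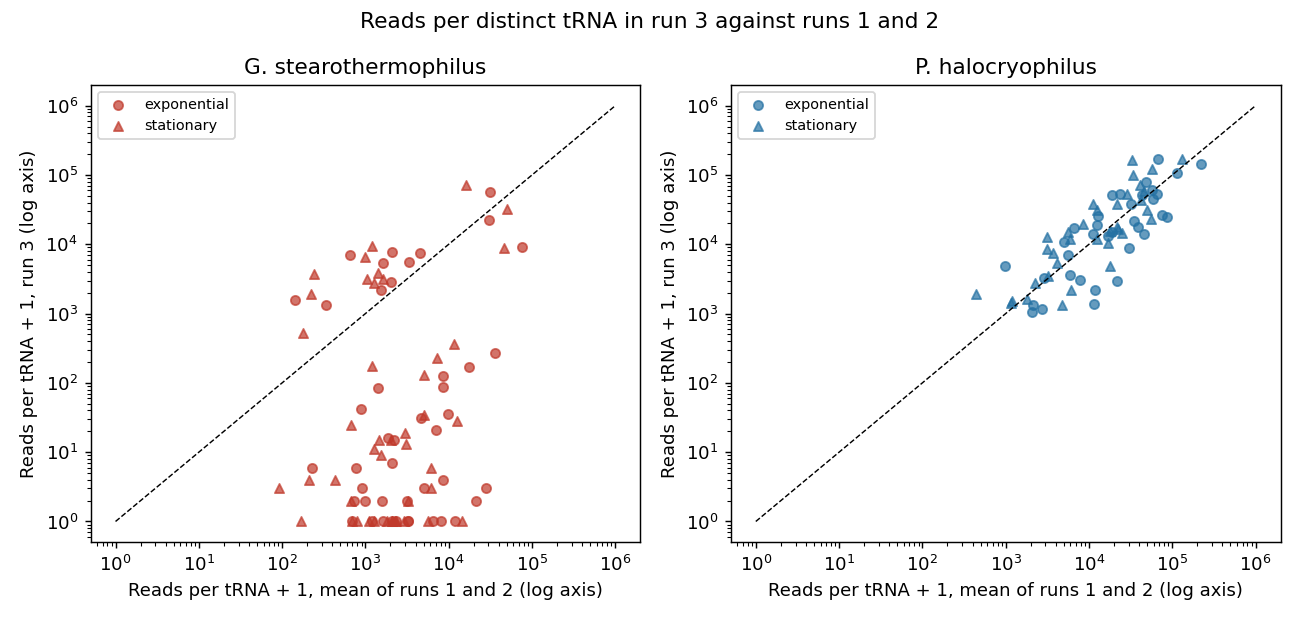
Reads per distinct tRNA plus 1 in run 3 (vertical, log axis) against the mean of runs 1 and 2 (horizontal, log axis), for exponential (circles) and stationary (triangles) libraries, with equality as a dashed line. In G. stearothermophilus 24 of 45 tRNAs in the exponential and 26 in the stationary library of run 3 were under 20 reads, and in P. halocryophilus 0 of 35.

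The first comparison set the cold-adapted and heat-adapted species against B. subtilis, the mesophilic reference named in the series. It concerned the shares of complete, incomplete and erroneous ends among the reads, which do not show how an end arose. Whether a gene itself encodes CCA was not examined, since no sequences were used here. Both cold-adapted species carried more erroneous ends, and stationary B. subtilis fewer complete ones. These were 7.29% ± 0.67 of reads in exponential and 5.86% ± 0.88 in stationary P. halocryophilus (SD, n = 3 each). In Exiguobacterium 255-15 they were 5.62% ± 0.59 and 5.23% ± 0.36 (n = 3 each). B. subtilis had 2.44% ± 0.31 (n = 3) and 1.91% ± 0.07 (n = 2), and G. stearothermophilus 2.25% ± 0.17 and 2.60% ± 0.63 (n = 3 each).

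Ends without any added base made up 2.94% and 3.75% of reads in exponential and stationary B. subtilis, 0.159% and 0.134% in P. halocryophilus, 0.339% and 0.173% in Exiguobacterium 255-15, and 4.72% and 0.722% in G. stearothermophilus. The last means rested on run 3 (13.7% and 2.04%), and in runs 1 and 2 they were 0.254% and 0.0624%. Ends with C alone made up 1.74% and 1.17% in P. halocryophilus, 1.36% and 1.52% in Exiguobacterium 255-15, and 2.57% and 1.55% in G. stearothermophilus, and CC ends 3.71% and 3.98%, 3.32% and 4.06%, and 3.87% and 4.06% in that order. Tails with a repeated CCA lay between 0.326% and 0.732% in all 8 groups.

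Averaged over phases, erroneous ends were higher than in B. subtilis by 4.40 percentage points in P. halocryophilus and by 3.25 in Exiguobacterium 255-15. In both cases the exact two-sided permutation p, with species labels exchanged within phase, was 0.005, the smallest that 200 arrangements allow, and 0.0135 after adjustment over 27 tests. The difference in G. stearothermophilus was 0.25 points (exact p = 0.48, adjusted 0.589), with 0.0799 when its stationary replicate 3 was left out and 0.389 when its stationary replicate 2 was. Tails that were neither repeats of CCA nor of the kind listed as D, CD or CCV made up 6.27% and 5.02% of reads in exponential and stationary P. halocryophilus. They made up 4.13% and 3.65% in Exiguobacterium 255-15 and 1.65% and 1.13% in B. subtilis. In G. stearothermophilus they made up 1.42% and 1.71%. The differences of 4.25 points in P. halocryophilus and 2.50 in Exiguobacterium 255-15 both had an adjusted exact p of 0.0135. Tails listed as D, CD or CCV, which are codes for ambiguous bases and are not explained in the sources used here, made up 0.864% and 0.852% in Exiguobacterium 255-15 and 0.322% to 0.45% in the other 6 groups, and were 0.472 points higher in Exiguobacterium 255-15 than in B. subtilis (adjusted exact p = 0.0135). Tails with a repeated CCA, a mark that the enzyme can add to unstable tRNAs, differed by 0.15 points in P. halocryophilus, 0.279 in Exiguobacterium 255-15 and 0.0847 in G. stearothermophilus (exact p = 0.425, 0.265 and 0.575). These tails varied with the run, from 0.0693% to 0.256% in run 3 and from 0.32% to 1.05% in runs 1 and 2. Within runs they were above B. subtilis in 5 of 5 pairs in Exiguobacterium 255-15 (0.0804 to 0.72 points) and in G. stearothermophilus (0.003 to 0.284), and in 4 of 5 in P. halocryophilus (−0.0145 to 0.45), where an exact test of 5 pairs cannot go below 0.0625.

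Incomplete ends were lower than in B. subtilis, with differences of −23.0 points in P. halocryophilus and −23.1 in Exiguobacterium 255-15 (exact p = 0.005 and adjusted p = 0.0135 each). In G. stearothermophilus the difference was −19.7 points (exact p = 0.055, adjusted 0.0825), and −21.5 points without exponential replicate 3 (adjusted exact p = 0.03). CC ends, which lack the terminal A alone, differed by −15.5 points in P. halocryophilus, −15.7 in Exiguobacterium 255-15 and −15.4 in G. stearothermophilus, with adjusted exact p of 0.027, 0.0225 and 0.0225. Complete ends differed by 18.6 points in P. halocryophilus (adjusted exact p = 0.0506), 19.9 in Exiguobacterium 255-15 (0.027) and 19.5 in G. stearothermophilus (0.0794). These calls turned on single libraries. P. halocryophilus passed without its exponential replicate 2 (19.1 points) or B. subtilis exponential replicate 2 (19.5), and G. stearothermophilus without its exponential replicate 3 (21.3). Exiguobacterium 255-15 no longer passed without any of its 3 stationary replicates, its exponential replicate 3, exponential B. subtilis replicate 1 or 3, or either stationary B. subtilis library (19.2 to 20.2 points). The differences were mostly those to the stationary B. subtilis libraries: with exponential libraries alone, incomplete ends differed by −5.47, −6.05 and 0.0855 points in that order (exact p = 0.1, 0.1 and 1, where 3 against 3 cannot go below 0.1).

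Replicate numbers marked a shared sequencing run, so each species was also compared with B. subtilis within runs. Erroneous ends were then higher in 5 of 5 pairs of libraries in P. halocryophilus, by 3.91 to 5.48 points, and in 5 of 5 in Exiguobacterium 255-15, by 2.92 to 3.59, while G. stearothermophilus ranged from −0.367 to 0.61. Complete ends ranged from −4.23 to 37.4 points in P. halocryophilus, −0.709 to 35.7 in Exiguobacterium 255-15 and −6.36 to 41.4 in G. stearothermophilus. With the replicate block, erroneous ends differed by 4.69 and 3.16 points in the 2 cold-adapted species, each with exact p = 0.0625, the smallest that 5 pairs allow, so that no call could be made.

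**Figure D2:**
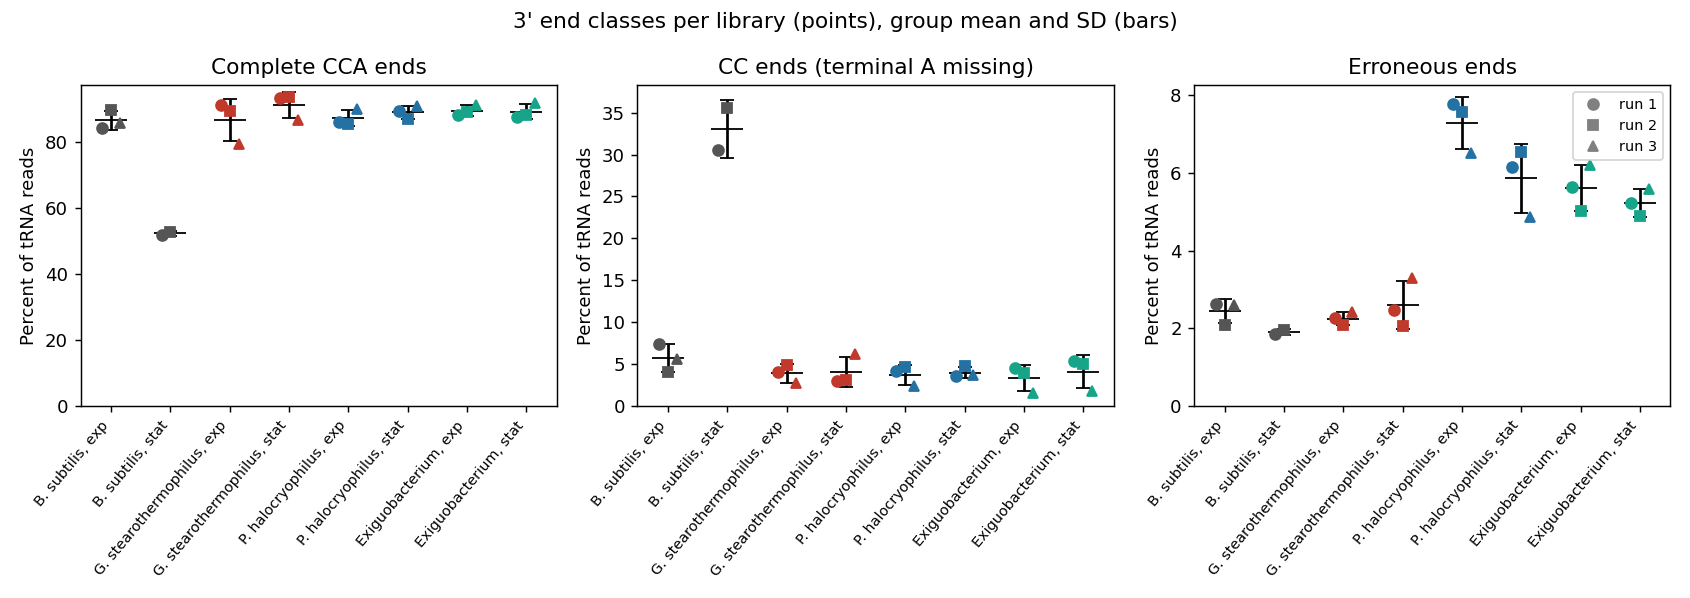
Percent of tRNA reads per library with complete CCA ends, CC ends and erroneous ends (vertical axes) in the 8 groups; symbols give the sequencing run, and bars the group mean and SD. Complete ends averaged 52.2% in stationary B. subtilis and 86.5% to 91.1% in the other 7 groups, and erroneous ends averaged 5.23% to 7.29% in the cold-adapted species and 1.91% to 2.60% in the others.

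The next comparison was of stationary with exponential phase within each species. In B. subtilis complete ends were 86.5% ± 2.88 in exponential (n = 3) and 52.2% ± 0.63 in stationary cultures (n = 2), a difference of −34.3 points. CC ends accounted for most of it, with 5.68% ± 1.67 in exponential and 33.0% ± 3.51 in stationary libraries, and C ends for 2.46% and 9.10%. Complete ends were lower by −32.4 and −37.1 points within the 2 runs that held both phases. The exact p was 0.1, the smallest that 3 against 2 allow. In P. halocryophilus complete ends were 87.1% ± 2.51 and 88.9% ± 1.94, in Exiguobacterium 255-15 89.4% ± 1.66 and 89.0% ± 2.22, and in G. stearothermophilus 86.6% ± 6.42 and 91.1% ± 3.92 (exponential then stationary, n = 3 each). Their differences of 1.76, −0.336 and 4.49 points did not pass (exact p = 0.3, 0.8 and 0.5) and moved with single libraries. The G. stearothermophilus difference was 0.814 without exponential replicate 3 and 6.76 without exponential replicate 1. In P. halocryophilus it was 0.865 without stationary replicate 3 and 3.20 without exponential replicate 3, and in Exiguobacterium 255-15 it lay between −1.61 and 0.571. Within runs, complete ends were higher in stationary phase in 3 of 3 runs in P. halocryophilus, by 0.653 to 3.30 points, and in 3 of 3 in G. stearothermophilus, by 2.06 to 7.31, while Exiguobacterium 255-15 ranged from −0.927 to 0.393, and 3 pairs are too few to pass 0.05 in an exact test. Over all species the difference in CC ends was 7.14 points (exact p = 0.0269, adjusted 0.211 over 9 end classes) and in complete ends −7.09 points (exact p = 0.137, adjusted 0.211). With the replicate block the pooled difference in complete ends was −4.70 points (exact p = 0.49, adjusted 0.5515).

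Erroneous ends differed between phases by −1.43 points in P. halocryophilus, −0.387 in Exiguobacterium 255-15, −0.534 in B. subtilis and 0.349 in G. stearothermophilus (exact p = 0.2, 0.4, 0.2 and 0.5). Single libraries moved these values. The range was −1.81 (without exponential replicate 3) to −0.934 (without stationary replicate 3) in P. halocryophilus and −0.688 (without exponential replicate 2) to −0.0962 (without exponential replicate 3) in Exiguobacterium 255-15. It was −0.712 (without exponential replicate 2) to −0.439 (without exponential replicate 1) in B. subtilis and 0.0075 (without stationary replicate 3) to 0.625 (without stationary replicate 2) in G. stearothermophilus. Within runs, P. halocryophilus was lower in stationary phase in 3 of 3 runs, by −1.65 to −1.02 points, Exiguobacterium 255-15 in 3 of 3, by −0.608 to −0.138, and B. subtilis in 2 of 2, by −0.775 and −0.126, while G. stearothermophilus was lower in 1 of 3 (−0.0265 to 0.872). In the pooled test over species the difference was −0.50 points (exact p = 0.056, adjusted 0.211), and −0.482 with the replicate block (exact p = 0.0654, adjusted 0.196).

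At the level of single tRNAs, complete ends fell in 35 of the 38 distinct tRNAs of stationary B. subtilis and rose in 0 (limma on log2 odds, adjusted p under the threshold of 0.05, median log2 change −2.32). Arg-ACG, Phe-GAA, Cys-GCA and His-GTG had the same standard error of 0.597, so the fit used a spread shared over tRNAs. Since tRNAs of the same library are not independent, these limma p-values do not replace the exact permutation p of 0.1 for whole libraries. Arg-ACG changed most, from 86.1% ± 5.28 complete ends (n = 3) to 31.1% ± 5.24 (n = 2), a log2 odds change of −3.86 (limma adjusted p = 9.67e-08), and 58.5% ± 6.38 of its stationary reads ended in CC. Phe-GAA went from 89.0% to 48.1% complete ends (log2 change −3.37), Cys-GCA from 85.1% to 37.8% (−3.33) and Val-TAC from 87.8% to 45.0% (−3.18). Trp-CCA, of which the anticodon and not the 3′ end is CCA, had the lowest stationary share, 25.2% ± 5.43, against 72.1% ± 10.6 in exponential cultures (log2 change −3.03). Its gene lies at positions 952397 to 952470 of the B. subtilis sequence, and that of Cys-GCA at 952781 to 952851 (genome build not given in the sources used here). Gln-TTG, Leu-TAG and Leu-GAG followed with log2 changes of −2.97, −2.85 and −2.80.

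The tRNAs with the highest stationary shares were His-GTG, with 95.4% ± 0.89 in exponential and 87.5% ± 0.62 in stationary cultures (log2 change −1.57, limma adjusted p = 0.0114), and Glu-TTC, with 86.7% ± 0.13 in stationary cultures. The 3 tRNAs not past the threshold, named after their values were seen, were Ile-GAT-1 (66.8% and 63.8%), Gly-TCC-1 (57.0% and 39.8%) and Ser-GCT (log2 change −1.08). Of the Met-CAT tRNAs, Met-CAT-2 went from 87.7% to 70.1%. The files do not say which Met-CAT gene is the initiator, so no value is given for it.

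**Figure D3:**
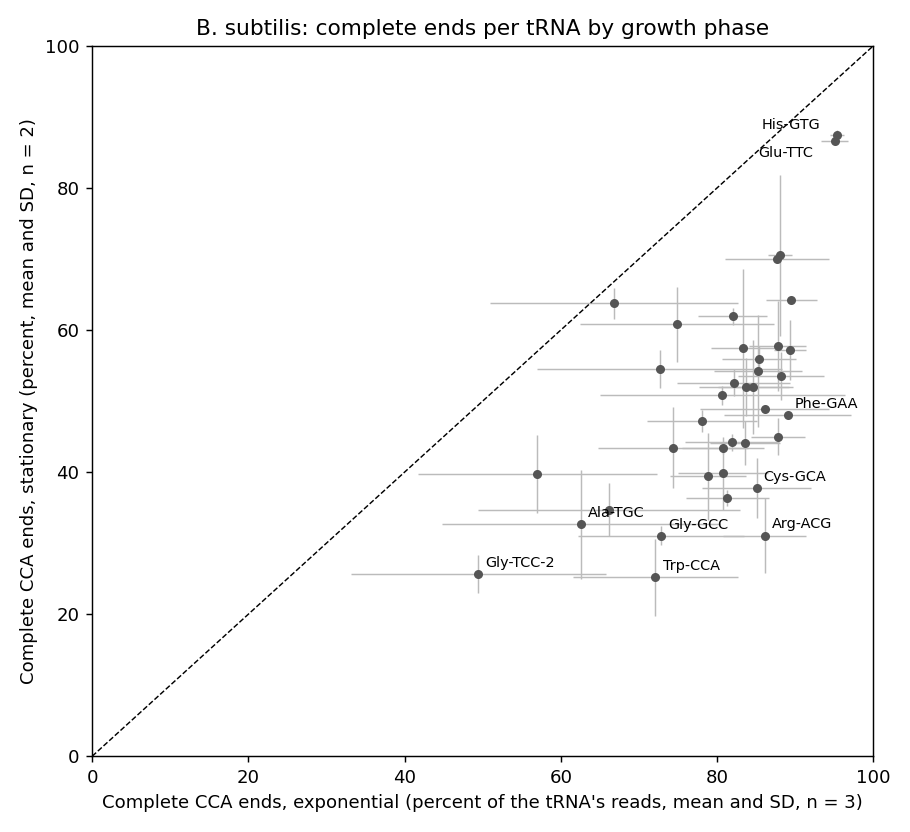
Share of each B. subtilis tRNA's reads with a complete CCA end in stationary (vertical, percent, mean and SD, n = 2) against exponential libraries (horizontal, percent, mean and SD, n = 3); points under the dashed line were lower in stationary phase. His-GTG and Glu-TTC stayed above 86% in stationary phase, while Trp-CCA averaged 25.2% and Arg-ACG 31.1%.

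All 7 amino acid groups fixed beforehand were lower in complete ends in stationary B. subtilis. Among the branched-chain tRNAs (Leu, Ile, Val) 8 of 9 fell, among the aromatic ones (Phe, Trp, Tyr) 3 of 3, among those with a long variable arm (Leu, Ser, Tyr) 8 of 9 and among the GUN anticodons that carry queuosine (Asn, Asp, His, Tyr) 5 of 5. Of acidic amino acids and amides 5 of 5 fell, of basic amino acids 6 of 6 and of small amino acids (Gly, Ala, Ser) 6 of 8, with the same counts when adjusted over the list alone. The fry test for movement in the same direction gave an adjusted p of 0.0282 to 0.031, and with the replicate block of 0.154 to 0.171, which ended these calls. No group passed the comparison with the other tRNAs (camera, adjusted p = 0.987 for all 7 with an estimated correlation).

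In the other species no tRNA passed the limma threshold for a phase difference in complete ends: 0 of 35 in P. halocryophilus, 0 of 37 in Exiguobacterium 255-15 and 0 of 45 in G. stearothermophilus, with 3, 2 and 3 at an unadjusted p under 0.05 and 0 in each by edgeR. For erroneous ends the limma counts were 0 in all 4 species (4 in B. subtilis, 2 in P. halocryophilus, 8 in Exiguobacterium 255-15 and 0 in G. stearothermophilus at an unadjusted p under 0.05; 0 in each by edgeR). Without replicate 3 of every group, also planned beforehand, 6, 6 and 10 tRNAs of P. halocryophilus, Exiguobacterium 255-15 and G. stearothermophilus passed for complete ends, of which 6, 4 and 8 rose in stationary phase. For erroneous ends 15, 11 and 0 passed in the same order and 9 in B. subtilis. Apart from erroneous ends in G. stearothermophilus, the counts of 0 therefore held for all runs together and not for runs 1 and 2 alone. With the replicate block, planned beforehand, 10 tRNAs of P. halocryophilus passed for erroneous ends, of which 9 fell in stationary phase, and 6 passed for complete ends. His-GTG was the largest of these: its erroneous share was 24.2% ± 0.70 in exponential and 11.6% ± 0.03 in stationary libraries of runs 1 and 2 (n = 2 each) and 11.9% and 7.33% in run 3. Its blocked log2 change was −1.11 (limma adjusted p = 0.00375), against an adjusted p of 0.497 without the block. Thr-TGT-1 (−0.87) and Val-TAC (−0.90) fell as well, and Thr-GGT rose (0.59). In B. subtilis the block gave 5 falls, among them Ala-TGC (−1.36) and Met-CAT-3 (−1.31), in Exiguobacterium 255-15 a single rise, of Trp-CCA (0.92), and in G. stearothermophilus 0. The tRNAs named from the block were chosen after their values were seen. In Exiguobacterium 255-15, 10 tRNAs passed for erroneous ends and 1 for complete ends without stationary replicate 3, and 3 for complete ends without exponential replicate 3; in B. subtilis 9 passed for erroneous ends without exponential replicate 3.

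His-GTG of Exiguobacterium 255-15 had 8.44% ± 0.66 erroneous ends in exponential and 4.41% ± 0.72 in stationary phase (n = 3 each, log2 change −1.01, limma adjusted p = 0.0742). Cys-GCA had 6.89% and 8.06% in P. halocryophilus, 3.39% and 3.11% in Exiguobacterium 255-15, and 2.78% and 2.57% in B. subtilis (limma adjusted p = 0.808, 0.818 and 0.85). Complete ends of His-GTG were 77.7% ± 8.31 and 88.1% ± 3.20 in P. halocryophilus and 88.7% ± 2.16 and 92.8% ± 0.60 in Exiguobacterium 255-15 (n = 3 each, limma adjusted p = 0.44 and 0.586). In G. stearothermophilus neither His-GTG nor Cys-GCA passed for complete or erroneous ends (limma adjusted p from 0.842 to 0.868). No amino acid group passed fry for erroneous ends in any species, whereas with the block the GUN anticodons of P. halocryophilus were lower in stationary phase (adjusted p = 0.00196; camera adjusted p = 0.806 with an estimated correlation, without the block).

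Whether the phase difference itself differed between species was examined against B. subtilis by exact permutation of phase labels within species. This permutation takes phase to have no effect in either species. Its p therefore does not test whether the phase differences of the species are equal. A stationary loss of complete ends as large as that in B. subtilis was absent from the means of the other species. The mean of Exiguobacterium 255-15 fell by 0.336 points. Within runs its incomplete ends were higher in stationary phase in 3 of 3 runs (0.216 to 1.06 points), as were its CC ends (0.273 to 1.04). The difference of differences in complete ends was 36.0 points in P. halocryophilus, 34.0 in Exiguobacterium 255-15 and 38.8 in G. stearothermophilus. The exact p were 0.015, 0.065 and 0.025, and 0.101, 0.176 and 0.135 after adjustment over 27 tests. None passed, which does not show that the phase differences are alike. For erroneous ends the differences were −0.896, 0.147 and 0.883 points (exact p = 0.37, 0.79 and 0.085). With 1 library left out they ranged from −1.28 (without exponential replicate 3) to −0.401 (without stationary replicate 3) in P. halocryophilus and from −0.154 (without exponential replicate 2) to 0.438 (without exponential replicate 3) in Exiguobacterium 255-15. In G. stearothermophilus they ranged from 0.541 (without stationary replicate 3) to 1.16 (without stationary replicate 2).

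Each species was then compared with B. subtilis anticodon by anticodon over both phases. The fit treats all libraries as independent, although libraries of the same number may share a culture. Its p-values, here and for complete ends and abundance below, do not replace the exact tests of whole libraries. Erroneous ends were higher in 27 of 31 anticodons in P. halocryophilus and in 20 of 32 in Exiguobacterium 255-15, and lower in 0 (limma, median log2 changes 1.52 and 1.20; 29 and 27 called by edgeR). His-GTG led in P. halocryophilus with 15.2% ± 7.23 erroneous ends (n = 6) against 1.87% ± 0.30 in B. subtilis (n = 5), a log2 change of 3.13 (limma adjusted p = 1.37e-05). tRNA-His is unusual in carrying an extra G at its 5′ end and a C before the CCA end in bacteria. Thr-TGT (10.6%, log2 change 2.82), Ile-GAT (7.72%, 2.52), Leu-GAG (9.88%, 2.43) and Ser-GCT (11.7%, 2.31) followed, then Asp-GTC (2.04), Val-GAC (2.00) and Leu-TAG (1.99). In Exiguobacterium 255-15 the largest changes were those of Tyr-GTA, with 19.2% ± 6.63 (n = 6; 2.49% ± 0.41 in B. subtilis; log2 change 3.18, limma adjusted p = 4.55e-08) and Ser-GGA, with 17.1% ± 4.92 (3.74% ± 0.98 in B. subtilis; 2.46). Tyr-GTA had 15.0% ± 0.40 in runs 1 and 2 (n = 4) and 27.7% ± 1.85 in run 3 (n = 2). The Ser-GGA gene lies at 704064 to 704154 of the Exiguobacterium 255-15 sequence. His-GTG (6.43%, 1.80), Lys-TTT (7.56%, 1.77), Trp-CCA (7.10%, 1.69), Asp-GTC (5.74%, 1.66), Ile-GAT (4.06% against 1.45%) and Arg-TCT (7.53%, 1.48) rose too. Cys-GCA was higher in P. halocryophilus (7.48% ± 3.21, log2 change 1.41, limma adjusted p = 0.011) and did not pass in Exiguobacterium 255-15 (3.25% ± 0.82, limma adjusted p = 0.625).

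**Figure D4:**
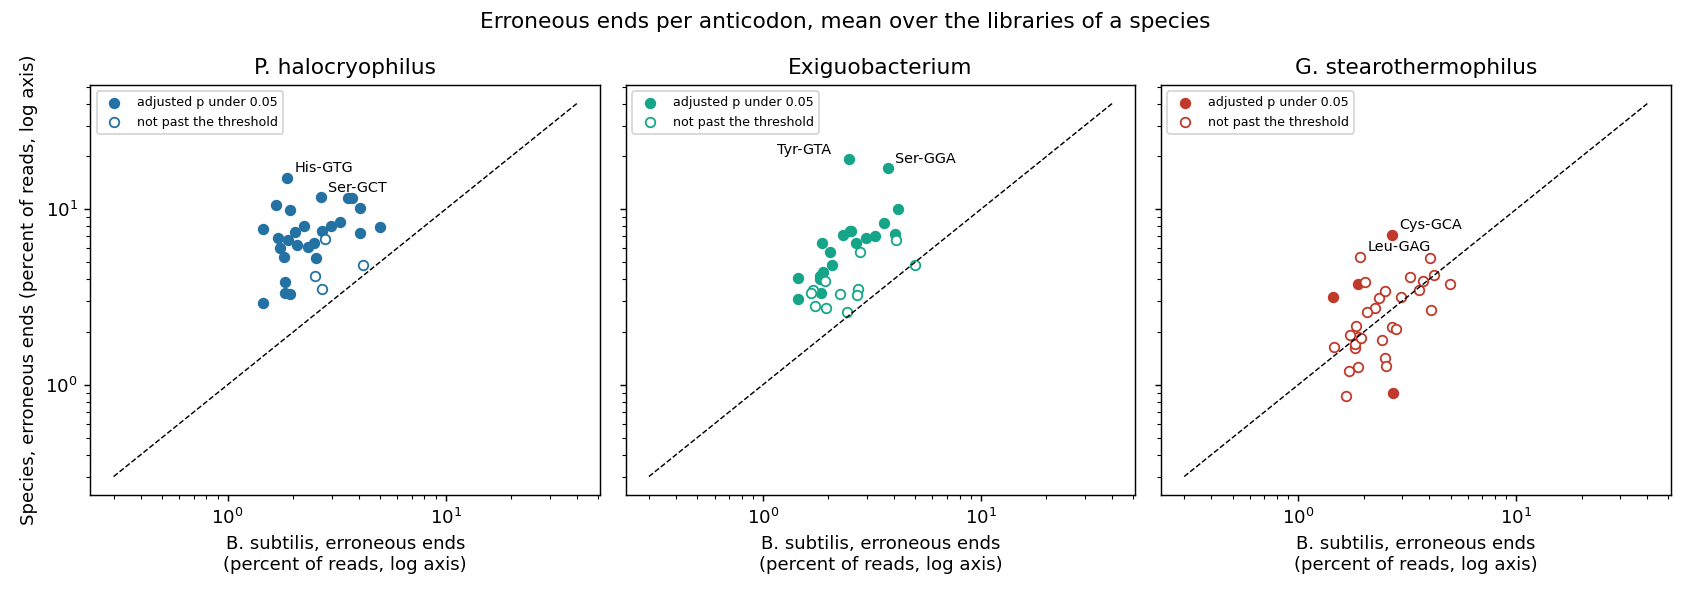
Percent of reads with an erroneous end per anticodon in each species (vertical, log axis) against B. subtilis (horizontal, log axis), as means over the libraries of a species; filled points had a limma adjusted p under 0.05, and the dashed line marks equality. His-GTG reached 15.2% in P. halocryophilus and Tyr-GTA 19.2% in Exiguobacterium 255-15. Ranked within each species by their erroneous share, Met-CAT-3 (15.5% ± 5.66), His-GTG and Thr-TGT-1 (13.8% ± 5.70) came first in P. halocryophilus, and Tyr-GTA, Ser-GGA and Met-CAT-3 (12.0% ± 4.38) in Exiguobacterium 255-15 (n = 6 each). In B. subtilis these were Met-CAT-3 (5.77% ± 3.15), Gln-TTG (4.99% ± 2.18) and Ala-GGC (4.19% ± 1.90; n = 5 each), and in G. stearothermophilus Cys-GCA, Met-CAT-2 (6.94% ± 2.26, n = 6) and Ala-CGC (5.66% ± 1.33, n = 4). Cys-GCA came first there through a run 3 library in which it had 5 reads, and without run 3 its share was 5.72%.

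All 7 amino acid groups were higher in erroneous ends in both cold-adapted species (fry adjusted p at most 0.000423 in P. halocryophilus and 0.00228 in Exiguobacterium 255-15). In P. halocryophilus all 7 branched-chain, 3 aromatic, 8 long-arm, 4 GUN and 4 acidic or amide anticodons rose, with 3 of 5 basic and 6 of 7 small ones. In Exiguobacterium 255-15 the counts were 4 of 8 branched-chain, 3 of 3 aromatic, 4 of 9 long-arm, 4 of 4 GUN, 3 of 4 acidic or amide, 4 of 5 basic and 5 of 7 small. Adjusted over the list alone they were the same, apart from 3 for the long-arm list of Exiguobacterium 255-15. Against the other tRNAs, the GUN list of Exiguobacterium 255-15 alone stood out with a preset correlation (camera adjusted p = 0.0429), which was lost with an estimated correlation (adjusted p = 0.229).

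In G. stearothermophilus 4 of 33 anticodons differed in erroneous ends (limma; 9 at an unadjusted p under 0.05, 2 by edgeR). Cys-GCA (7.14% ± 6.97, n = 6, log2 change 1.83), Val-GAC (1.12) and Ile-GAT (1.10) were higher, and Arg-CCG lower (0.903% ± 0.20, n = 4, against 2.72% ± 0.81; −1.52), with adjusted p of 0.0213 to 0.0359. Cys-GCA had 5 and 2 reads in the libraries of run 3 and 5.72% ± 2.50 erroneous ends in the other 4. Ile-GAT did not pass without stationary G. stearothermophilus replicate 1 or exponential replicate 3. The count was 0 without either stationary B. subtilis library, 1 without stationary G. stearothermophilus replicate 3, 2 without exponential B. subtilis replicate 1 or 2, and 1 (Arg-CCG, which was lower) with both libraries of run 3 left out, an alternative chosen after seeing the data. None of the 7 amino acid groups passed fry (adjusted p from 0.155 to 0.861), with 2 of 8 branched-chain anticodons higher and 1 of 6 basic anticodons lower.

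Complete ends over both phases were higher than in B. subtilis for 26 of 31 anticodons in P. halocryophilus, 27 of 32 in Exiguobacterium 255-15 and 28 of 33 in G. stearothermophilus (limma, median log2 changes 1.64, 1.80 and 1.88). Gly-TCC had 91.0% ± 2.78 complete ends in P. halocryophilus (n = 6) against 45.8% ± 15.9 in B. subtilis (n = 5), a log2 change of 3.77 (limma adjusted p = 7.85e-05), followed by Trp-CCA (3.05), Gly-GCC (2.91), Ala-TGC (2.83), Asp-GTC (2.52), Leu-TAA (2.46), Cys-GCA (2.38) and Arg-ACG (2.32). In Exiguobacterium 255-15 Gly-GCC (91.6% ± 1.36 against 56.1% ± 24.1, log2 change 3.29), Cys-GCA (3.26), Ile-GAT (3.09), Asp-GTC (3.03), Ala-TGC (3.01), Trp-CCA (2.81), Gly-TCC (2.80) and Gln-TTG (2.69) led. In G. stearothermophilus these were Trp-CCA (2.72), Gly-TCC (2.71, CCC included), Arg-ACG (2.69), Arg-CCG (2.63), Tyr-GTA (2.50), Asp-GTC (2.49), Leu-CAA (2.48) and Gly-GCC (2.48), and Cys-GCA rose by 1.64. His-GTG was the single anticodon that was lower, in P. halocryophilus, with 82.9% ± 8.03 against 92.2% ± 4.36 (log2 change −1.19, limma adjusted p = 0.0101). With stationary libraries alone, chosen after seeing the data, its direction reversed, with a log2 change of 0.12. It did not pass in Exiguobacterium 255-15 or G. stearothermophilus (limma adjusted p = 0.522 and 0.0938).

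All 7 amino acid groups were higher in complete ends in all 3 species by fry, with adjusted p from 0.000111 to 0.0482, and none by camera with an estimated correlation (lowest adjusted p = 0.825). Separate fits by phase, chosen after seeing the data, gave 0 anticodons past the limma threshold in exponential libraries in all 3 species (6, 7 and 4 at an unadjusted p under 0.05) and 29, 32 and 33 in stationary libraries. For erroneous ends the same fits gave 19 and 25 anticodons in P. halocryophilus, 8 and 19 in Exiguobacterium 255-15 and 0 and 2 in G. stearothermophilus (exponential, then stationary).

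The abundance of each tRNA among all tRNA reads was compared between phases. No tRNA passed the edgeR threshold in any species. The count was 0 of 38 in B. subtilis, 0 of 35 in P. halocryophilus, 0 of 37 in Exiguobacterium 255-15 and 0 of 45 in G. stearothermophilus, with 6, 0, 4 and 0 at an unadjusted p under 0.05 and 2, 0, 2 and 0 by DESeq2. With the replicate block 17 B. subtilis tRNAs passed, 8 higher and 9 lower in stationary phase. These calls rest on the phase differences within runs 1 and 2, since exponential replicate 3 has no stationary partner. Each tRNA thus has few libraries from which its own spread can be estimated. Glu-TTC fell most, from 23.5% ± 2.69 of tRNA reads in exponential to 8.22% ± 0.11 in stationary libraries of runs 1 and 2 (n = 2 each, blocked log2 change −1.78, edgeR adjusted p = 3.09e-05). Tyr-GTA (−1.13), His-GTG (−1.02) and Phe-GAA (−0.90) fell as well. Trp-CCA rose from 0.413% ± 0.01 to 0.981% ± 0.01 (0.98, edgeR adjusted p = 0.000261), with Arg-CCG (0.96), Asp-GTC (0.92), Gly-TCC-2 (0.79) and Gly-GCC (0.76).

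These B. subtilis counts turned on exponential replicate 3, the library in which His-GTG took 35.4% of reads: without it 21 tRNAs passed, 12 higher and 9 lower. The libraries then left are those on which the blocked phase differences rest, so these counts are not separate support. Leaving out replicate 3 of every group removes the same library in B. subtilis. In Exiguobacterium 255-15 the block gave 0, and 1 passed without stationary replicate 3. In G. stearothermophilus the block gave Arg-CCT (−2.01) and Arg-TCT (−1.08). With replicate 3 of every group left out, the counts were 21 in B. subtilis, 0 in P. halocryophilus, 20 in Exiguobacterium 255-15 (Leu-CAG 1.13 higher, Met-CAT-3 −2.54) and 13 in G. stearothermophilus (Glu-TTC 1.64 higher, Arg-CCT −1.91). Of the amino acid groups, the GUN and the acidic or amide tRNAs of Exiguobacterium 255-15 were lower in stationary phase by fry (adjusted p = 0.0328 and 0.00327), with no member past the threshold and an adjusted p of 0.556 and 0.51 by camera with an estimated correlation. With the block, GUN tRNAs were lower and acidic or amide and small ones higher in B. subtilis (limma's fry, adjusted p = 0.0479 each), although Glu-TTC, an acidic member, fell most. None of these lists stood out from the other tRNAs (camera, adjusted p = 0.971 each with an estimated correlation, without the block). His-GTG and Cys-GCA did not pass in any species in the fits without the block (edgeR adjusted p from 0.283 to 0.999).

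Abundance was compared between species over the 31 anticodons shared by all 4. Lys-TTT was higher in P. halocryophilus, with 8.98% ± 1.29 of tRNA reads (n = 6) against 0.726% ± 0.42 in B. subtilis (n = 5; log2 change 3.70, edgeR adjusted p = 0.0462), and Glu-TTC lower, with 5.23% ± 2.16 against 15.1% ± 7.96 (−1.34, edgeR adjusted p = 0.0145). In Exiguobacterium 255-15 Phe-GAA (3.64% ± 0.93 against 0.893% ± 0.22; 2.11) and Val-GAC (1.68) were higher. In G. stearothermophilus Val-GAC was higher (1.55% ± 0.41 against 0.399% ± 0.05; 2.35, edgeR adjusted p = 0.000961) and Cys-GCA lower (0.033% ± 0.03 against 0.326% ± 0.10; −2.88, edgeR adjusted p = 0.0247). His-GTG did not pass in any species (edgeR adjusted p = 0.937, 0.954 and 0.862).

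These were 2 of 31 anticodons in each species (7, 7 and 9 at an unadjusted p under 0.05; 5, 11 and 9 by DESeq2), and 4, 2 and 6 with the replicate block. Without replicate 3 of every group the counts were 24, 26 and 23, with Lys-TTT (3.77) and Ala-GGC (−2.87) leading in P. halocryophilus, Tyr-GTA (2.83) and Ala-GGC (−2.32) in Exiguobacterium 255-15, and Trp-CCA (−2.36) and Arg-CCG (2.28) in G. stearothermophilus. Leaving out any single library gave 0 or 1 in P. halocryophilus, where Lys-TTT was never called and Glu-TTC not without either stationary B. subtilis library or exponential B. subtilis replicate 1, 0 to 2 in Exiguobacterium 255-15 (0 without exponential replicate 3, either stationary B. subtilis library or exponential B. subtilis replicate 3) and 1 to 6 in G. stearothermophilus (6 without stationary replicate 2, and 1 without exponential replicate 2 or either stationary B. subtilis library). By limma's fry, acidic or amide anticodons were lower in P. halocryophilus (adjusted p = 0.0166), aromatic ones higher in Exiguobacterium 255-15 (0.000315), and long-arm and small ones lower in G. stearothermophilus (0.0327 each). With an estimated correlation in camera the adjusted p were 0.52, 0.468, 0.746 and 0.746. With the replicate block the aromatic anticodons of P. halocryophilus passed as well (limma's fry, adjusted p = 0.0212, against 0.0549 without it).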

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

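The tests of run, abundant tRNAs, handling, repeated CCA tails, precursor tails and run 3 were chosen only after the results were seen, as were the counts over other splits of the libraries. The test without the 3 tRNAs of highest erroneous share was set before.

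Complete CCA ends differed between phases by −34.3 points in B. subtilis, 1.76 in P. halocryophilus, −0.336 in Exiguobacterium 255-15 and 4.49 in G. stearothermophilus (0.814 without exponential replicate 3), a difference between groups that was taken as a difference of differences against B. subtilis. It was 36.0 points for complete, −35.2 for incomplete and −7.22 for C ends in P. halocryophilus, and 38.8, −39.7 and −7.67 points in G. stearothermophilus, with exact p between 0.005 and 0.045 and adjusted p between 0.101 and 0.176. The permutation takes phase to have no effect in either species, so these p do not test whether the phase differences are equal. Without exponential replicate 3 of G. stearothermophilus the 38.8 points became 35.1, and in Exiguobacterium 255-15 complete ends gave 34.0 points (exact p = 0.065). The sequencing run does not account for the loss, since the smaller of the within-run differences was 32.4 points, nor do a few abundant tRNAs, since 37 of 38 tRNAs were lower in both runs. Loss of the terminal base during RNA handling may account for the 27.4 points more CC ends. The labels give both phases the same protocol, but they were harvested at different times, and no value here separates the handling of the stationary B. subtilis samples from their growth phase. A biological difference of growth phase, such as less repair of 3′ ends by the nucleotidyltransferase in stationary cells, also stays open and was not tested.

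Cold-adapted species carried more erroneous ends in every library than any B. subtilis library. Without repeated CCA tails the lowest cold-adapted library still lay 1.34 points above the highest B. subtilis library, and without the 3 tRNAs of highest erroneous share of each species 1.15 points, which argues against repeated CCA and a few tRNAs as the whole cause. Tails of precursor tRNAs stay open. In run 3 of P. halocryophilus the erroneous share kept at least 0.766 of its level in the other runs while reads called unprocessed kept at most 0.175 of theirs, but the labels do not say what that column holds, no sequences were used here, and run 3 cannot be told apart from rRNA depletion. Lower fidelity of the nucleotidyltransferase in cold-adapted species may explain these ends, but growth at 20 °C and species cannot be separated here, mapping and genome differences were not tested, and only 2 cold-adapted species were sampled.

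Most tRNAs were nearly missing from the G. stearothermophilus libraries of run 3. Low depth does not account for it, since at the composition of runs 1 and 2 their depth would leave 0 tRNAs under 20 reads. As to a depletion that removes tRNAs in every species, 0 tRNAs of the other species were under 20 reads in run 3. Those libraries held 451245 to 1165634 reads, against 131360 and 149129 in the exponential and stationary G. stearothermophilus libraries. A partial removal could leave tRNAs above 20 reads at that depth, so an effect of depletion is left open. Reads of another organism could be the source and are left open. In the exponential library the highest Spearman correlation was 0.26 with the species' own runs and 0.226 with another species in run 3, and in the stationary library it was 0.251 and 0.282. Neither library reached the difference of 0.2 set for a decision, and the highest values taken over both libraries differed by −0.022. No biological explanation was tested, since no group of the design sets these libraries apart.

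Reads called unprocessed, a column outside the comparisons, stood above the B. subtilis level in both cold-adapted species. Per 1000 reads, with both summed over gene copies, their means were 0.739 and 0.712 in exponential and stationary Exiguobacterium 255-15, and 2.02 and 2.40 in P. halocryophilus, against at most 0.0744 in any B. subtilis library. They are not particular to these species: stationary G. stearothermophilus had a mean of 0.139, with 0.38 in replicate 1 and no more than 0.0362 in the other stationary replicates.

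Calls were also counted over other splits of the libraries into groups of the same sizes. For erroneous ends in P. halocryophilus 1 of 100 splits, the real one, gave as many calls (27, highest other 22). The same held in Exiguobacterium 255-15 (1 of 100, with 20, highest other 17). Chance would be excluded for these counts only if libraries were exchangeable. Libraries of the same replicate number were not independent of each other, and for the shares per library neither the replicate block (smallest exact p 0.0625) nor phases averaged per number (0.1) allows a call. Chance is therefore left open here. For complete ends in P. halocryophilus the share was also under 0.05 (1 of 100; 27, other 26), but by a margin of 1 call, with 22 calls without stationary B. subtilis replicate 2 and 0 with exponential libraries alone (limma; 6 at an unadjusted p under 0.05), so it is not read as beyond chance. Chance cannot be excluded for complete ends in Exiguobacterium 255-15 (7 of 100; 27, other 29) and G. stearothermophilus (13 of 100; 28, other 33). For abundance it cannot be excluded in G. stearothermophilus (10 of 100; 2, other 4). Shares under 0.05 that rest on single libraries were those for erroneous ends in G. stearothermophilus (3 of 100; 4, other 8) and for abundance in P. halocryophilus (2 of 100; 2, other 2) and Exiguobacterium 255-15 (1 of 100; 2, other 0). In G. stearothermophilus the count was 0 without either stationary B. subtilis library, 1 without stationary replicate 3 and 2 without exponential B. subtilis replicate 1 or 2. In P. halocryophilus it was 0 without either stationary B. subtilis library or exponential B. subtilis replicate 1, and 1 without any other library. In Exiguobacterium 255-15 it was 0 without exponential replicate 3, either stationary B. subtilis library or exponential B. subtilis replicate 3. These counts are therefore not read as beyond chance. Between phases within P. halocryophilus, Exiguobacterium 255-15 and G. stearothermophilus, the 10 splits are too few for a share under 0.05: the real count was 0 by limma or edgeR in each of the 9 tests, so that all 10 splits gave as many, and the highest other count was 6 for erroneous ends in P. halocryophilus, 4 for erroneous ends in Exiguobacterium 255-15 and 0 in the other 7 (counts at an unadjusted p under 0.05 and by the other tool stand in the report).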

How the results depend on the processing

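Fits of exponential or stationary libraries alone and those without the G. stearothermophilus libraries of run 3 were chosen after seeing the data, and the other settings before. Of library shares, 516 alternatives kept direction and side of the threshold, 34 were weaker, 7 stronger and 16 reversed; of counts of calls, 276 stayed within 1.5 times and 71 moved; of named tRNAs, 1079 stayed, 87 were weaker and 1 reversed; shares of named tRNAs all stayed; of list counts, 5 stayed and 13 moved. Among library shares, the phase tests within a species cannot go below an exact p of 0.1. They could not change side of the threshold, so part of the 516 was fixed in advance. Values are percentage points or counts of calls, the comparisons are with B. subtilis unless phases are named, and the cause was not tested except where fewer libraries raise the smallest p.

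With each tRNA weighted equally, P. halocryophilus complete ends passed at 21.6, and the phase differences of Exiguobacterium 255-15 reversed (complete 0.325, incomplete −0.554, erroneous 0.228). Without ends that lack any added base, Exiguobacterium 255-15 complete ends no longer passed (17.8), while G. stearothermophilus did (complete 19.7, incomplete −19.9). On log2 odds the P. halocryophilus difference of phase differences in erroneous ends reversed to 0.0121.

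Settings whose smallest p is too large for a call kept their direction: without replicate 3 of every group (smallest p 0.0556), P. halocryophilus incomplete −22.1 and erroneous 4.88, Exiguobacterium 255-15 complete 18.5, incomplete −21.6 and erroneous 3.06; with the replicate block (0.0625), −19.4, 4.69, 15.9, −19.1 and 3.16 in that order; with phases averaged per replicate number (0.1), −17.4, 4.28, 14.3, −17.4 and 3.13; with stationary libraries only, −40.6, 3.95, 36.8, −40.2 and 3.32; with exponential libraries only, −5.47, 4.85, 2.88, −6.05 and 3.18. With the last, G. stearothermophilus reversed in incomplete (0.0855) and erroneous ends (−0.191).

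Among counts, edgeR on both counts gave 2 for G. stearothermophilus erroneous ends. For abundance between species, DESeq2 size factors gave 5 in Exiguobacterium 255-15 and 17 in G. stearothermophilus, the DESeq2 test 5 in P. halocryophilus, 11 in Exiguobacterium 255-15 and 9 in G. stearothermophilus, and complete ends only 4 in P. halocryophilus and 0 in Exiguobacterium 255-15 (edgeR; 10 at an unadjusted p under 0.05). Between phases the DESeq2 test gave 2 in B. subtilis and 2 in Exiguobacterium 255-15. The replicate block gave, between phases, 5 (B. subtilis erroneous), 6 and 10 (P. halocryophilus complete and erroneous) and 1 (Exiguobacterium 255-15 erroneous), in abundance 17 (B. subtilis) and 2 (G. stearothermophilus), and between species in abundance 4 (P. halocryophilus) and 6 (G. stearothermophilus); it moved no other count. Without replicate 3 of every group the phase counts were 9 (B. subtilis erroneous), 6 and 15 (P. halocryophilus complete, erroneous), 6 and 11 (Exiguobacterium 255-15) and 10 (G. stearothermophilus complete), in abundance 21 (B. subtilis), 20 (Exiguobacterium 255-15) and 13 (G. stearothermophilus), and between species 9 (G. stearothermophilus erroneous) and in abundance 24, 26 and 23. Without the run 3 libraries of G. stearothermophilus its counts were 10 (phase, complete), 13 (phase, abundance), 1 (species, erroneous) and 17 (species, abundance). With exponential libraries only, complete ends gave 0, 0 and 0 (limma; 6, 7 and 4 at an unadjusted p under 0.05) and erroneous ends 8 in Exiguobacterium 255-15 and 0 in G. stearothermophilus (2 unadjusted); with stationary libraries only, 2 in G. stearothermophilus. His-GTG complete ends of P. halocryophilus reversed to 0.12 (log2) with stationary libraries only.

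Of lists that moved by fry, those past camera were 0 for phase complete ends (preset and estimated correlation; 0 by blocked fry), 1 preset and 0 estimated for phase abundance (5 by blocked fry), 0 and 0 for species complete ends, 1 and 0 for species erroneous ends and 0 and 0 for species abundance, and blocked fry gave 1 for phase erroneous ends. Camera asks a different question from fry.

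Leaving out 1 library at a time gave ranges of 17.9 to 19.5 for complete ends in P. halocryophilus, 19.2 to 20.7 in Exiguobacterium 255-15 and 18.4 to 21.3 in G. stearothermophilus, and −21.5 to −18.6 for its incomplete ends. Phase differences ranged from −1.61 to 0.571 (Exiguobacterium 255-15 complete), −0.475 to 2.18 (incomplete), −1.39 to 0.348 (P. halocryophilus incomplete), 0.865 to 3.20 (P. halocryophilus complete) and 0.814 to 6.76 (G. stearothermophilus complete), and the difference of differences in Exiguobacterium 255-15 erroneous ends from −0.154 to 0.438. Counts ranged from 0 to 1 (P. halocryophilus), 0 to 2 (Exiguobacterium 255-15) and 1 to 6 (G. stearothermophilus) for species abundance, 0 to 6 for G. stearothermophilus erroneous ends, and between phases 0 to 3 and 0 to 10 (Exiguobacterium 255-15 complete and erroneous), 0 to 9 (B. subtilis erroneous), 0 to 21 (B. subtilis abundance) and 0 to 1 (Exiguobacterium 255-15 abundance). Reads per tRNA, not the total of 131360 and 149129 reads, limit the exponential and stationary G. stearothermophilus libraries of run 3, where 24 and 26 of 45 tRNAs had under 20 reads.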

Other observations

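The test of abundance against loss was set before its result was seen.

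The log2 odds change of complete ends between phases in B. subtilis ranged from −3.86 in Arg-ACG to −0.29 in Ile-GAT-1, which did not pass. The hypothesis that abundant tRNAs lose more was tested over the 38 distinct tRNAs, with log2 reads in exponential libraries against the log2 odds change. It was not borne out: Pearson's r was 0.104 and Spearman's rho 0.12 (two-sided permutation p of r = 0.534). This is a relation across tRNAs, which are not independent replicates.

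Gly-TCC-2 of B. subtilis, singled out after its values were seen, had 49.4% ± 16.4 complete ends in exponential (n = 3) and 25.6% ± 2.66 in stationary libraries (n = 2), and 37.9% and 32.6% of its reads had no added base.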
